A study of Homo sapiens with 3 samples.

How the data were processed

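The series holds 3 two-channel Agilent expression arrays of A549 cells. Per the labels, channel 1 (Cy3, green) held RNA from empty-vector cells and channel 2 (Cy5, red) RNA from Aiolos cells on each array, and the design text states that the 3 cultures of each kind were grown and harvested independently. Total RNA was labelled through a polyadenylation, amplification and Klenow reaction with Cy-dye nucleotides, per the labels' protocols. The scanner files hold spot and local background intensity values as deposited by the authors, with no normalization. They also hold the processed intensity of each channel, which Feature Extraction had background-subtracted, detrended and dye-normalized (linear and LOWESS) per the file headers, with surrogate values near background. A log10 ratio of red over green per spot was computed by the same program, per the file headers. The submitters' processing notes give Agilent Feature Extraction version 11, while the file headers give 10.7.3.1. Other deposited columns were flags of background, outlier and saturation. Coordinates are those of the files, whose headers name hg19.

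The authors' deposited value table gives log2 ratios of red over green. Set against the scanner files, its scale is the log2 of the program's own ratio and its direction is Cy5 over Cy3. Its column medians were -0.05, -0.02 and -0.02, so no further centring was applied. It left 11970, 22346 and 16762 cells empty for replicates 1, 2 and 3, by a rule that is not given in the sources used here, and it served as an alternative only.

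Each array had 62976 spots, of which 4259 were controls, and 50599 probes. Gene names came from the probe's RefSeq accession through a RefSeq table of a later human assembly for 28174 probes, used for names only, and from the file for 18031; 4394 probes had no gene name. Mean signals were corrected with normexp (offset 50) against the median local background and normalized within each array by loess in limma 3.58.1 under R 4.3.3. Control spots and spots with an outlier flag (961, 485 and 648 spots in replicates 1, 2 and 3) had no weight, outlier spots were left out of a probe's mean, and spots of a probe were averaged. Median signals were 551, 262 and 269 in green and 910, 404 and 345 in red. A probe was tested if well above background on 3 of 3 arrays in at least 1 channel, which kept 27744 probes (24946 of them in each channel). A probe whose spots on an array all had an outlier flag counted as not above background there, whatever its brightness. The alternative that kept dim probes also admitted such probes. A gene was read from its brightest tested probe. Of 5022 genes with over 1 tested probe, 295 had probes that passed in opposite directions.

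The test was limma's lmFit and eBayes of the mean log2 ratio against 0, two-sided, over 3 arrays, with Benjamini-Hochberg adjustment and a threshold of 0.05; n is 3 throughout, and the SD is that of 3 array ratios. Each array pairs an Aiolos culture with an empty-vector culture, so the pairing comes from the shared array. Gene lists were tested with limma's camera at its preset correlation over the 44 lists, each with at least 3 measured members, with the estimated correlation and fry beside it. For a gene not above background on any array in 1 channel, the fold is a bound: the bright channel's mean against the dim channel's mean of the higher, per array, of the lowest signal above background and the gene's own, after loess and Aquantile. Such bounds and all ratios are open to dye bias, since the orientation was the same throughout. On simulated data with the spread of these 18762 genes, in which 200 genes changed, the test recovered 24% of changes of 0.5 on the log2 scale, 78% of those of 1, 92% of those of 2 and 100% of those of 4, with 3 false calls. In the real data 12806 genes passed, so the adjustment asked for a smaller p in the simulation. These shares therefore do not measure the recovery in the real data.

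Replicate 1 lay on slide 1 and scan 1, replicates 2 and 3 on slide 2 and scan 2. The groups, the tests, the lists and the rule for naming genes were set before the data were examined. The rule named IKZF3 and SHC1 with their probes; the 10 largest rises and 10 largest falls among genes that passed with the same sign on 3 arrays, above background in each channel, clone-type names left out; up to 4 members with the smallest p in each list that passed and in 10 lists on adhesion, junctions, survival, mesenchymal state and the IKAROS and SHC families; up to 2 in each list of other cell types; and the 3 highest and 3 lowest of the bounds. The alternatives were no background correction, an offset of 16, the program's processed signals with and without loess, median centring, scaling between arrays, other filters on dim probes, separate channels without the array, a trended and robust eBayes, a test against a fold of 1.5, the authors' table, leaving out each replicate, the mean of a gene's probes, other list tests, and, added after seeing the data, removal of the trend on probe GC content. Some members that the rule named are withheld for evaluations and are left out of the text.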

Results

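RNA was measured from A549 cells, a human lung adenocarcinoma epithelial line, that had received either an expression vector for Aiolos or the empty vector. Aiolos is the protein of IKZF3, a zinc finger transcription factor of the IKAROS family best known from lymphocytes. The labels give 3 Aiolos cultures and 3 empty-vector cultures, grown and harvested independently. Each of 3 arrays carried 1 culture of each kind, with the empty-vector RNA in green (Cy3) and the Aiolos RNA in red (Cy5). The dyes were not exchanged on any array, so an effect of the dye on a given probe stays in its ratio. In the empty-vector channel, 75.1%, 53.1% and 65.2% of the probes lay well above background in replicates 1, 2 and 3, and in the Aiolos channel 70.8%, 53.1% and 61.9%. No spot was saturated. The log2 ratios of the tested probes correlated across probes at r = 0.956 between replicates 1 and 2, 0.939 between 1 and 3 and 0.964 between 2 and 3; genes within an array are not independent replicates, and the number of arrays limits the precision.

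The study's title names p66Shc, the longest protein product of SHC1, and growth without anchorage, so SHC1 was read first after the transfected gene itself. The IKZF3 signal gave no check of the transfection. Its single probe, A_23_P376060 (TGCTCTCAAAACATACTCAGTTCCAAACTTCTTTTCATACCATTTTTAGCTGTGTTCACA, chromosome 17, 37921911 to 37921970 in hg19), was not well above background in either channel on any array, at a log2 ratio of -0.04 ± 0.06 (SD, n = 3). Whether that probe lies inside the part of the gene carried by the vector is not given in the sources used here, and a probe outside it would see nothing of the construct. Directions therefore rest on the labels of the channels.

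SHC1, which encodes adaptor proteins of receptor tyrosine kinase signalling, fell with Aiolos. Probe A_23_P200443 (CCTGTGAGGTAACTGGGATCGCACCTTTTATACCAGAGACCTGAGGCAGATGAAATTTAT, chromosome 1, 154935081 to 154935140 in hg19, 10 spots per array) read -1.29 ± 0.12 on the log2 scale (SD, n = 3), or 2.45-fold lower, with a limma adjusted p of 1.05e-05. Probe A_24_P68585 (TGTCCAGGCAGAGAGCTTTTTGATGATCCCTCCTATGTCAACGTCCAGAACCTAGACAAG, chromosome 1, between 154938501 and 154938644) read -1.27 ± 0.17, adjusted p = 1.93e-05. Each of the probes was lower on 3 of 3 arrays. The files list the p66Shc transcript NM_183001 for each probe together with other SHC1 transcripts, so neither reading separates p66Shc from the shorter Shc proteins of the same gene. With the arrays centred on their median in place of loess, the first probe read -0.84. Among its relatives, SHC4 fell (-1.42 ± 0.15, adjusted p = 7.96e-06, above background in the Aiolos channel on 2 arrays) and SHC3 fell (-1.34 ± 0.44, adjusted p = 0.000228). SHC2 rose by a smaller amount (0.39 ± 0.19, adjusted p = 0.00652), with an adjusted p of 0.0552 without replicate 2 and from 0.00227 to 1 over the alternatives. As a set, the SHC family had 3 members lower and 1 higher, also when adjusted over the list alone, and the set did not pass camera's test (adjusted p = 0.215). Of the other IKAROS family members, IKZF4 fell (-0.58 ± 0.10, adjusted p = 0.000366) and IKZF5 rose (0.42 ± 0.11, adjusted p = 0.00202). IKZF2 rose by 0.22 ± 0.15 (adjusted p = 0.0421), a call lost without replicate 1 (0.17 from a second probe that was then the brightest, adjusted p = 0.108) or without replicate 2 (0.23, adjusted p = 0.151), with adjusted p from 0.0181 to 1 over the alternatives. The IKAROS list of 3 measured genes, with 2 higher and 1 lower over all genes and adjusted over the list alone, did not pass (adjusted p = 0.850).

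**Figure D1:**
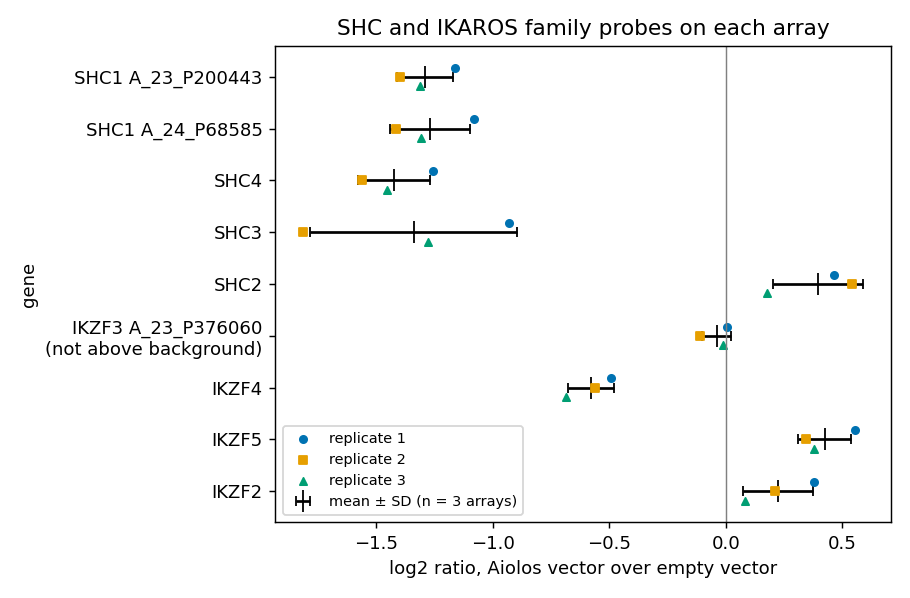
Log2 ratios of Aiolos over empty vector (x axis) for each measured SHC and IKAROS family gene (y axis), 1 marker per replicate array, with the mean and SD over 3 arrays as a black tick and bar. Each SHC1 probe lies below 0 on 3 of 3 arrays, while the IKZF3 probe, not above background, lies at 0 within its SD.

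The Aiolos channel and the empty-vector channel differed in most of the genes that could be measured, with any dye effect included. Of 18762 genes tested, 12806 (68.3%) passed limma's test, 6337 higher and 6469 lower with Aiolos, and 12767 of them had the same sign on 3 of 3 arrays. Most of these differences were small: the median absolute log2 ratio of the genes that passed was 0.55, and 2910 genes changed at least 2-fold (1510 higher, 1400 lower) and 227 at least 8-fold (137 higher, 90 lower). Protein-coding genes gave 9843 of 14040, and unannotated long intergenic RNAs with XLOC names 1282 of 2077. At the level of probes 18441 of 27744 passed, 8915 higher and 9526 lower. Tested against a fold of 1.5, the count was 3814 genes, and in a fit that set the channels against each other without the array it was 3553. Centring each array on its median in place of loess moved the median of all genes to 0.13 and the share of higher genes among those that passed from 49.5% to 62.3%, with 7608 higher and 4599 lower. Within the slide that held replicates 2 and 3, 12700 genes passed; the other slide held replicate 1 alone, which allows no test.

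Among genes above background on 3 arrays in each channel, the largest rises were TRIM31, a ubiquitin ligase, and the immediate early transcription factors EGR1 and FOS. TRIM31 was 76.6-fold higher (6.26 ± 0.23, SD, n = 3), EGR1 56.8-fold (5.83 ± 0.07) and FOS 55.3-fold (5.79 ± 0.11), each with a limma adjusted p of 8.69e-08. CCN3, a matricellular protein, rose by 5.67 ± 0.15, SCEL, a cornified envelope protein, by 5.35 ± 0.28 and the serpin SERPINB7, in a 10 Mb window of chromosome 18 with a median of 0.48, by 5.20 ± 0.23. OAS1, an interferon-induced oligoadenylate synthetase, rose by 5.02 ± 0.09, glutamine synthetase (GLUL) by 5.00 ± 0.02, the transmembrane glycoprotein GPNMB by 4.99 ± 0.14 and the AP-1 subunit FOSB by 4.83 ± 0.06. The largest falls among the same kind of genes were KIRREL3, an immunoglobulin superfamily adhesion protein, which was 48.6-fold lower (-5.60 ± 0.23, adjusted p = 1.06e-07), and ACKR3, an atypical chemokine receptor, at -5.10 ± 0.27. The cytokine IL11 fell to -4.53 ± 0.35, the branched-chain aminotransferase BCAT1 to -4.53 ± 0.05, the proteoglycan SPOCK1 to -4.51 ± 0.06 and the junctional protein JCAD to -4.48 ± 0.11. The bradykinin receptor BDKRB2 stood at -4.48 ± 0.12, the calcium-binding protein S100A3 at -4.46 ± 0.13, the neurotrophin receptor NTRK3 at -4.40 ± 0.60 and the teneurin TENM2 at -4.31 ± 0.25. NTRK3 had the highest adjusted p of these 20 genes, 2.84e-06.

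**Figure D2:**
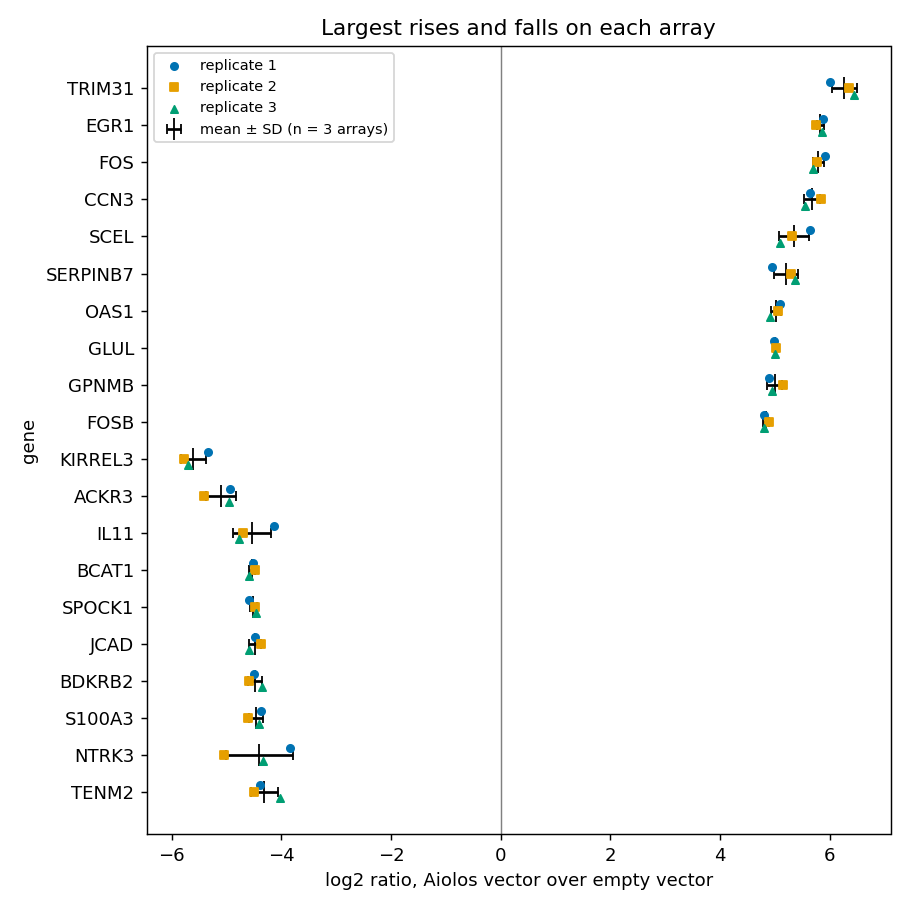
Log2 ratios of Aiolos over empty vector (x axis) for the 10 largest rises and 10 largest falls among genes above background on 3 arrays in each channel (y axis), 1 marker per replicate array, with the mean and SD over 3 arrays as a black tick and bar. TRIM31 lies at 6.26 and KIRREL3 at -5.60, and the replicates of each gene lie on the same side of 0.

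Some genes were above background in a single channel and have only a lower bound for their fold. CST2, a secreted cystatin, was at least 20.2-fold higher with Aiolos, the antiviral enzyme RSAD2 at least 17.8-fold and the adhesion molecule NCAM1 at least 14.4-fold, with limma adjusted p of 4.07e-07, 2.63e-05 and 4.01e-06. Integrin beta 3 (ITGB3) was at least 13.9-fold lower (adjusted p = 1.23e-05), the metalloprotease ADAMTS6 at least 9.80-fold (adjusted p = 1.81e-07) and the acetylcholine receptor subunit CHRNA9 at least 5.48-fold (adjusted p = 1.71e-05). For CST2 the bound equals the measured log2 ratio of 4.34, because its own empty-vector signal was the higher of the 2 used. Such bounds remain open to dye bias.

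Of 44 gene lists, 13 passed limma's camera at its preset correlation, 8 higher and 5 lower with Aiolos. No list passed with an estimated correlation, at an adjusted or at an unadjusted threshold of 0.05, while fry, which asks only whether a list's genes move one way, called 39. In simulated data with 3 arrays a list shifted by 0.5 on the log2 scale also failed with an estimated correlation (adjusted p = 0.188). The simulated genes were drawn independently. In the 13 lists that passed, the estimated correlation ran from -0.08 for the fibroblast markers to 0.23 for the ribosomal proteins. With 3 arrays this test can thus miss a shifted list that has no correlation between its genes. The fibroblast and interstitial matrix lists had estimated correlations of -0.077 and -0.0027. Their unadjusted camera p was 0.0038 each at the preset correlation, and 0.094 and 0.085 with the estimate. Correlation between genes therefore does not explain the failure of these lists. For lists with a positive estimate the simulation does not tell why they failed. Members that moved against the rest of their list are named below because of their values.

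**Figure D3:**
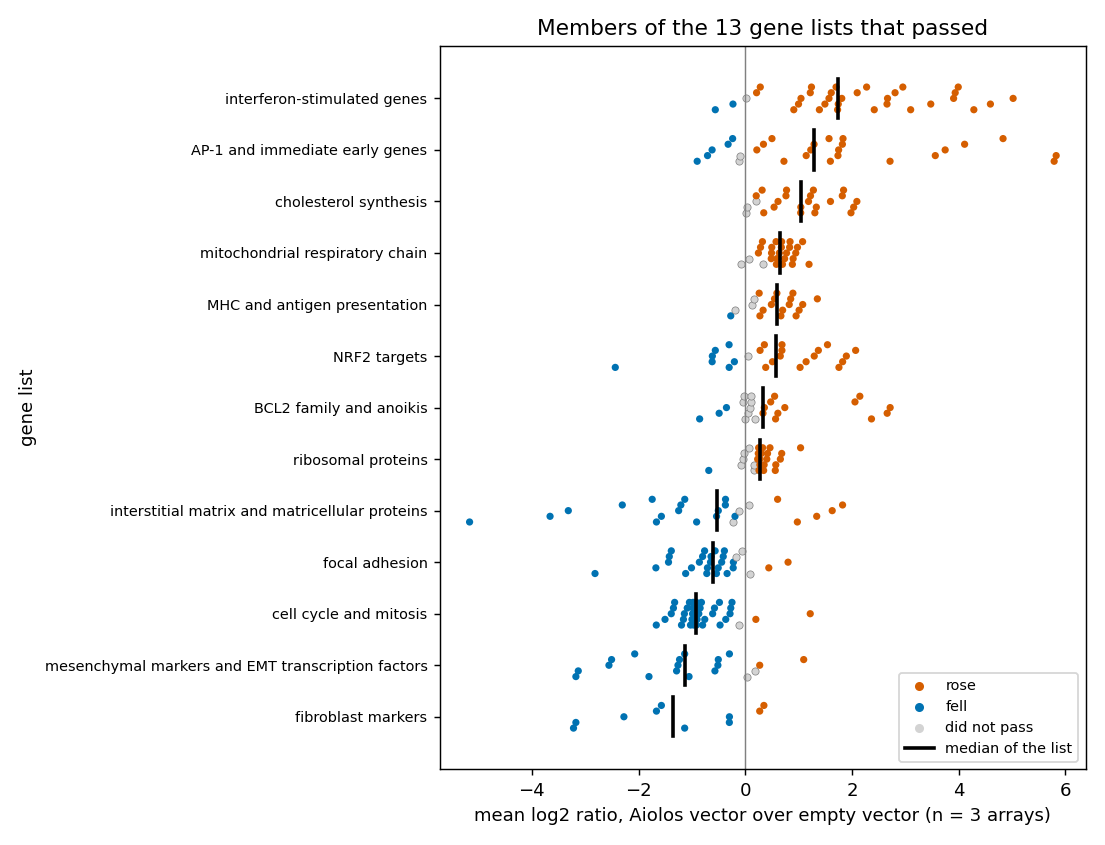
Mean log2 ratios over 3 arrays (x axis) of the members of the 13 lists that passed camera (y axis), each point a gene coloured by whether it rose, fell or did not pass, with a black bar at the list's median. The medians run from 1.74 for the interferon-stimulated genes to -1.35 for the fibroblast markers.

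Genes of the interferon response rose together. Of 33 interferon-stimulated genes measured, 30 rose and 2 fell, over all genes and adjusted over the list alone, with a median of 1.74 and 26 of them at least 2-fold up (camera adjusted p = 8.77e-11). The list reached adjusted p = 0.510 with an estimated correlation. Beside OAS1, the antiviral proteins IFIT1 (4.59 ± 0.06), IFIT3 (3.90 ± 0.02) and MX1 (3.93 ± 0.23) had the smallest p. MX2 was among those that fell (-0.23), and OAS3 did not pass (0.02). Of 19 genes of MHC and antigen presentation, 15 rose and 1, the proteasome subunit PSMB8, fell (-0.27), with the same counts when adjusted over the list alone (median 0.59, camera adjusted p = 0.000878). That list had adjusted p = 0.510 with an estimated correlation. B2M, the light chain of class I molecules, rose by 1.35 ± 0.14, HLA-B by 0.89 ± 0.11 and HLA-G, in a 10 Mb window of chromosome 6 with a median of 0.33, by 0.95 ± 0.15. The class I heavy chains are alike in sequence, and cross-hybridisation between them was not tested.

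Immediate early genes, which respond to growth factors and stress without new protein synthesis, rose as a group. Among 27 measured AP-1 and immediate early genes 20 rose and 5 fell, over all genes and adjusted over the list alone (median 1.29, camera adjusted p = 0.000162). The list reached adjusted p = 0.510 with an estimated correlation. EGR1, FOS, FOSB and the nuclear receptor NR4A2 (3.75 ± 0.18) had the smallest p. IER3 (-0.90), IER5 (-0.71), FOSL1 (-0.62), MYC (-0.32) and SPRY4 (-0.24) fell.

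Cell cycle genes fell. Of 38 measured, 35 fell and 2 rose, over all genes and adjusted over the list alone, with a median of -0.92 (camera adjusted p = 1.48e-08). Its value was adjusted p = 0.510 with an estimated correlation. CDC20, an activator of the anaphase-promoting complex, read -1.67 ± 0.05, the mitotic kinase AURKB -1.50 ± 0.08, CDK2 -1.39 ± 0.07 and topoisomerase TOP2A -1.32 ± 0.05. The cyclins CCND1 (1.22) and CCND3 (0.20) rose, and CDC6 did not pass (-0.12). Of 7 measured inhibitors of cyclin-dependent kinases, 4 rose and 1 fell, also when adjusted over the list alone, and that list did not pass (adjusted p = 0.0917), but did with dim probes kept (adjusted p = 0.0252) and in the fit of separate channels without the array (adjusted p = 0.0444), in a range from 0.0252 to 0.119 over the alternatives.

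Genes of focal adhesions, which couple integrins to actin, fell. Of 28 measured, 23 fell and 2, paxillin (PXN, 0.80) and TES (0.44), rose, over all genes and adjusted over the list alone (median -0.60, camera adjusted p = 0.000107). This group had adjusted p = 0.510 with an estimated correlation. Parvin alpha (PARVA) fell to -2.82 ± 0.11, the actin cross-linkers ACTN1 to -1.68 ± 0.17 and FLNA to -1.42 ± 0.11, and the scaffold NEDD9 to -1.39 ± 0.14. The integrins themselves went each way. Of 21 measured, 8 rose and 10 fell, also when adjusted over the list alone, and the list did not pass (adjusted p = 0.546). ITGB7 (2.67 ± 0.16) and ITGAX (2.42 ± 0.22) rose, while ITGA5, the alpha chain of the fibronectin receptor (-2.82 ± 0.27), and ITGA10 (-2.48 ± 0.16) fell.

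Mesenchymal and matrix genes were lower with Aiolos. Of 19 mesenchymal markers and EMT transcription factors, 15 fell and 2, S100A4 (1.09) and TWIST1 (0.27), rose, over all genes and adjusted over the list alone (median -1.14, camera adjusted p = 0.000355). Camera gave adjusted p = 0.510 with an estimated correlation. The gelatinase MMP2 (-3.17 ± 0.12, above background in the Aiolos channel on 2 arrays), the collagen cross-linking enzyme LOXL2 (-2.51 ± 0.04), the transcription factor SNAI1 (-3.13 ± 0.26) and the receptor kinase AXL (-2.07 ± 0.09) fell. Of 24 interstitial matrix and matricellular genes, 16 fell and 5 rose, over all genes and adjusted over the list alone (median -0.52, camera adjusted p = 0.0154). This list too had adjusted p = 0.510 with an estimated correlation. CCN3 (5.67 ± 0.15), entered in the list under its older symbol NOV, was not matched to it. The counts, the median and the test therefore leave out this rise. SPARC (-5.17 ± 0.11, above background in the Aiolos channel on 2 arrays), collagen COL5A1 (-3.32 ± 0.15), tenascin TNC (-3.66 ± 0.25) and versican VCAN (-2.31 ± 0.07) fell, while COL12A1 (1.82), COL8A1 (1.63, above background in the empty-vector channel on 1 array), SPP1 (1.34), CCN1 (0.98) and ELN (0.61) rose. Of 26 laminin, hemidesmosome and basement membrane genes, 7 rose and 15 fell, also when adjusted over the list alone, and the list did not pass (adjusted p = 0.227), with a median of -0.22 that became 0.01 with median centring. Type IV collagens divided within it: COL4A1 (-2.70 ± 0.18) and COL4A2 (-2.13 ± 0.10) fell and COL4A4 (2.23 ± 0.15) rose, as did the laminin chain LAMB3 (2.19 ± 0.14).

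Markers of fibroblasts, included to look for other cells, fell. Of 10 measured among 17, 8 fell and 2, FBLN2 (0.35) and TWIST1 (0.27), rose, over all genes and adjusted over the list alone (median -1.35, camera adjusted p = 0.0154). Fibroblast markers had adjusted p = 0.510 with an estimated correlation. Other lists hold 7 of these 10 genes. MMP2 and TWIST2 (-1.14 ± 0.05) fell. FAP was at least 3.04-fold lower and COL3A1 at least 2.34-fold, since neither was above background in the Aiolos channel on any array, and with such members at their bound the median was -1.18. Among genes above background in each channel, a filter that removes members whose Aiolos signal is dim, the median was -0.30 and the list did not pass (adjusted p = 0.643). With the authors' processed signals the median was -1.58 and the list did not pass either (adjusted p = 0.0769, or 0.0746 after loess), and over the alternatives adjusted p ran from 0.000434 to 0.643. Of 8 measured B lymphocyte genes 2 rose and 1 fell, of 4 T and NK lymphocyte genes 3 rose, of 10 myeloid markers 4 rose and 1 fell, and of 7 endothelial markers 4 rose and 1 fell, with the same counts adjusted over the list alone, and none of these lists passed (adjusted p = 0.919, 0.212, 0.449 and 0.303). Median and test differed in sign from the mean for the B lymphocyte list (median 0.02, mean -0.07). EBF1 fell (-1.60 ± 0.16) and IGLL1 rose (0.63 ± 0.12) among the B lymphocyte genes, CD8A (0.78 ± 0.32, above background in the empty-vector channel on 2 arrays) and CD7 (0.41 ± 0.16) rose among the T and NK genes, CD14 fell (-2.69 ± 0.23) and ITGAX rose among the myeloid markers, and MMRN2 (4.06 ± 0.23, above background in the empty-vector channel on 2 arrays) rose among the endothelial markers. PECAM1 was at least 2.81-fold higher, not above background in the empty-vector channel on any array.

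Cadherin and tight junction genes had no common direction, while most desmosome genes rose without their list passing. Of 18 cadherins, catenins and nectins, 8 rose and 6 fell, also when adjusted over the list alone, and the list did not pass (adjusted p = 0.551). The carcinoembryonic antigen family members CEACAM6 (4.05 ± 0.08) and CEACAM1 (3.68 ± 0.23) rose, and NECTIN2 (-2.21 ± 0.13) and the catenin CTNND1 (-1.47 ± 0.04) fell. Of 22 tight junction genes, 10 rose and 10 fell, also when adjusted over the list alone (adjusted p = 0.884). CLDN2 (-2.83 ± 0.03) and CGNL1 (-1.84 ± 0.07) fell, and TJP3 (2.43 ± 0.10) rose. Of 9 desmosome genes 7 rose and 2, EVPL (-0.53) and PKP4 (-0.51), fell, also when adjusted over the list alone, but the list missed the threshold (adjusted p = 0.0721) and passed without replicate 1 (adjusted p = 0.0466) or without replicate 2 (adjusted p = 0.0462), with median centring (adjusted p = 0.0436) and with separate channels (adjusted p = 0.0481), in a range from 0.0436 to 0.138 over the alternatives. DSC2 (1.57 ± 0.19, above background in the empty-vector channel on 2 arrays), DSC3 (1.55 ± 0.24), PKP2 (1.57 ± 0.34) and DSG2 (0.87 ± 0.15) rose. DSC2, DSC3 and DSG2 lie between 20 and 30 Mb of chromosome 18 (hg19), where the median over 29 genes was 0.41.

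Metabolic genes of sterol synthesis and respiration rose. Of 23 cholesterol synthesis genes 20 rose and none fell, and 21 rose when adjusted over the list alone (median 1.04, camera adjusted p = 7.92e-07). Sterol synthesis had adjusted p = 0.510 with an estimated correlation. The sterol sensor partner INSIG1 (2.03 ± 0.10), the sterol carrier STARD4 (1.82 ± 0.03) and the isoprenoid enzyme IDI1 (1.84 ± 0.10) rose. Of 26 respiratory chain genes 23 rose and none fell, and 24 rose when adjusted over the list alone (median 0.66, camera adjusted p = 7.99e-06). It had adjusted p = 0.510 with an estimated correlation. The cytochrome oxidase subunits COX7A2 (1.20 ± 0.17), COX5B (0.95 ± 0.13) and COX6C (0.98 ± 0.19) and the complex I subunit NDUFB5 (0.83 ± 0.04) rose. Of 24 NRF2 targets, which serve oxidant defence, 16 rose and 7 fell, over all genes and adjusted over the list alone (median 0.58, camera adjusted p = 0.0425). NRF2 targets had adjusted p = 0.510 with an estimated correlation, and adjusted p = 0.0705 with the authors' processed signals after loess, in a range from 0.000645 to 0.0705 over the alternatives. The peroxidase GPX2 (1.82 ± 0.06), thioredoxin reductase TXNRD1 (1.76 ± 0.05) and OSGIN1 (1.89 ± 0.24) rose, while the aldo-keto reductase AKR1B10 (-2.44 ± 0.03) fell.

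Of 25 ribosomal protein genes 18 rose and 1, RPS20 (-0.68 ± 0.18), fell, over all genes and adjusted over the list alone (median 0.28, camera adjusted p = 0.0154). The list had adjusted p = 0.591 with an estimated correlation, and it missed the threshold with the authors' processed signals (adjusted p = 0.0889, or 0.161 after loess) and with their table (adjusted p = 0.0915), in a range from 8.44e-06 to 0.161 over the alternatives. Among 10000 random lists matched on brightness, 93.95% had a median no higher than that of this list, so a minority of equally bright sets rose more. RPS2 (1.04 ± 0.27), RPS4X (0.66 ± 0.15) and RPL30 (0.57 ± 0.08) rose. RPS2 and RPS4X, however, had another probe that passed in the opposite direction. The RPS20 probe was much dimmer, at a mean log2 brightness of 9.28 against 15.6, 15.9 and 15.5 for RPS2, RPS4X and RPL30. RPS20 read 0.63 through another, brighter probe when the filter on dim probes was lifted. Over the alternatives limma's adjusted p reached 0.427 for RPS2, 0.718 for RPS4X and 0.548 for RPS20.

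Genes of the BCL2 family and of anoikis, the death of detached cells, rose more often than they fell. Of 23 measured, 12 rose and 3, BOK (-0.86), BNIP3 (-0.49) and BCL2L2 (-0.35), fell, over all genes and adjusted over the list alone (median 0.33, camera adjusted p = 0.0179). These death and survival genes had adjusted p = 0.510 with an estimated correlation. The genes with the smallest p promote cell death or serve metabolism: the BH3-only genes PMAIP1 (2.37 ± 0.06) and BIK (2.15 ± 0.05), the death-associated kinase DAPK2 (2.66 ± 0.21) and the pyruvate dehydrogenase kinase PDK4 (2.06 ± 0.08). Values for BCL2L1 (-0.02), MCL1 (0.11) and BCL2L11 (0.11), named here because of them, did not pass.

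Genes of cell death and stress were mixed. Of 25 death receptors and caspases, 13 rose and 7 fell, with 8 lower when adjusted over the list alone (camera adjusted p = 0.275). For the lists that follow in this paragraph the counts over all genes and adjusted over the list alone were equal unless both are given, and none passed camera. Of 26 p53 targets 11 rose and 4 fell (median 0.13, adjusted p = 0.0721), but the list passed with median centring (median 0.54, adjusted p = 0.018) and with dim probes kept (adjusted p = 0.0252), in a range from 0.018 to 0.11 over the alternatives. Of 18 other antioxidant enzymes 11 rose and 5 fell (adjusted p = 0.275), and of 29 genes of the unfolded protein response and ATF4 8 rose and 16 fell (adjusted p = 0.320). Of 17 heat shock proteins 4 rose and 7 fell, 3 and 7 adjusted over the list alone (adjusted p = 0.343). Hypoxia and glycolysis had 8 higher and 15 lower of 29, 9 and 15 adjusted over the list alone (adjusted p = 0.320). Fatty acid synthesis had 11 higher and 5 lower of 23 (adjusted p = 0.210). The chromatin remodelling partners of IKAROS proteins had 3 higher and 14 lower of 28 (adjusted p = 0.140), and passed with the mean of a gene's probes (adjusted p = 0.0429) and with dim probes kept (adjusted p = 0.0489), in a range from 0.0429 to 0.689 over the alternatives. The lists of the unfolded protein response, heat shock, hypoxia and these partners had medians that turned positive with median centring. Housekeeping genes had 10 higher and 4 lower of 18, 10 and 5 adjusted over the list alone (median 0.23, adjusted p = 0.320). With median centring the housekeeping median was 0.86 and the list passed (adjusted p = 0.0101), in a range from 0.0101 to 0.523 over the alternatives.

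Signalling and lineage genes had no common direction that passed. Under the same convention, YAP and TEAD targets had 6 higher and 13 lower of 25 (camera adjusted p = 0.212), TGF-beta and SMAD genes 10 higher and 15 lower of 29 (adjusted p = 0.320) and Notch genes 8 higher and 7 lower of 20 (adjusted p = 0.449). Wnt genes had 14 higher and 12 lower of 31, 15 and 13 adjusted over the list alone (adjusted p = 0.978), with a median of 0.07 and a test direction of up beside a mean of -0.07. NF-kB and inflammatory genes had 15 higher and 13 lower of 31 (adjusted p = 0.959), with a median of -0.05 and a mean of -0.16 beside a test direction of up. Lung epithelial lineage genes had 4 higher and 8 lower of 20 (adjusted p = 0.303), stemness factors 4 higher and 6 lower of 14 (adjusted p = 0.583) and gap junction genes and protocadherins 8 higher and 4 lower of 14 (adjusted p = 0.387). Keratins had 5 higher and 7 lower of 15 (adjusted p = 0.919), with a median of -0.09 and a test direction of down beside a mean of 0.29. Matrix proteases and their inhibitors had 12 higher and 13 lower of 29, 13 and 13 adjusted over the list alone (adjusted p = 0.528), with a median of 0.03 beside a mean of -0.39 and a test direction of down.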

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

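The tests of inflammatory genes, of the IKZF3 probe and of the trend on probe GC content were added after the data were seen, the last before its own result was.

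The spike-in control spots carried a signal that no comparison above used. All 10 E1A spike-in sequences, 35 spots each, were well above background on 100% of spots in each channel, against 0.758% (green) and 0.974% (red) of 308 negative control spots per array. Their mean log2 ratios of red over green after loess ran from -0.49 to 3.23, 8 of 10 were higher in red on 3 of 3 arrays, and the ratios correlated between arrays over the spike-ins at r of at least 0.991. The amounts added to each channel are not given in the sources used here.

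That 12806 of 18762 genes differed between the channels was weighed against technical explanations. Flipping the sign of 1 array gave 0 changed genes at the most by limma (12, 1 and 5 at an unadjusted threshold), and only 1 of the 4 sign patterns, the real one, reached its count; with 4 patterns the share cannot go under 0.05. Bias of single probes towards a dye, as the main source, is argued against by second probes of another sequence. These correlated with the first at r = 0.841 over 3418 changed genes (95% bootstrap bounds 0.824 and 0.857). Of these second probes 87.2% had the same sign and 2453 also passed in the same direction, so that such bias stays open for single genes. Overlap between the sequences of a gene's probes was not measured, and the genes were chosen through the first probe. The argument therefore holds only as far as the sequences differ. A trend on probe GC content is argued against by the 12868 genes that passed after its removal. Copy number differences as the main source are argued against by the windows of 10 Mb with shifted medians, which held 1.79% of the changed genes, but 5 of 281 windows were shifted where shuffled genes gave 0.28, so that a part in those windows stays open. Another line with an intact 9p21 region in 1 channel stays open, although no probe pointed to the region in 1 channel alone. A CDKN2A (0.09) and an MTAP probe (-0.21) read above background on 3 arrays in each channel although A549 cells lack the region. For that reason 0 probes differing by 2-fold decided nothing. The other MTAP and CDKN2A probes were above background on 0 arrays in either channel. Dye effects shared by all probes of a transcript, slow differences between the cultures and an effect of Aiolos stay open too. No array exchanged the dyes, and no array compared empty vector with itself.

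IKZF3 had 0 probes above background in the Aiolos channel. A probe that lies outside the transfected part and a low level of the transcript cannot be told apart with 1 probe and no map of the construct.

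The rise of interferon-stimulated genes was set against 2 sources. For a general inflammatory response, the NF-kB and inflammatory list had a median of -0.0533, with 95% bootstrap bounds of -0.404 and 0.595. The upper bound lay under the interferon list's median of 1.74. These bounds argue against a rise of the list as a whole like that of the interferon list. A response of part of its genes stays open. Of 31 members 15 rose and 13 fell, with an SD of 1.77. They ran from IL11 (-4.53) to IL1A (3.13, above background in the empty-vector channel on 2 arrays). NF-kB targets such as BIRC3 (2.50), ICAM1 (1.83) and TNFAIP3 (1.07), chosen after their values were seen, rose. Induction of an interferon ligand gene stays open. Of 16 ligand genes on the array 3 were above background in the Aiolos channel on 3 arrays. Of these 1, IFNE, was higher there, at 0.48 (limma adjusted p = 0.000901), and it was above background in the empty-vector channel on 3 arrays too. Over all tested genes 6337 of 18762 were higher, so 1 of 3 does not set the ligands apart from other genes. IFNB1 was not above background on any array. An effect of Aiolos and a difference between the cultures in their response to vector DNA, which both received, were not tested.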

How the results depend on the processing

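Of the alternatives, only the removal of the GC trend was chosen after seeing the data. Slide as a random block was not run, because 3 arrays leave too few for limma to estimate its correlation. Without the array pairing (no replicate block, separate channels) 4540 probes and 3553 genes passed. Against a fold of 1.5 it was 5121 probes and 3814 genes. All of these genes were also among the 12806. The fit without pairing left the mean ratios as they were (SHC1 at -1.29 in each fit). Signal differences between arrays that the channels share, which cancel in a ratio, stayed in its spread. The count against a fold of 1.5 follows from its stricter null. Other settings, the replicates left out among them, kept each count within 1.5 times. Without each replicate in turn the counts ran from 14442 to 18266 probes, 10131 to 12700 genes and 13 to 14 lists; SHC1 ran from -1.36 to -1.24, its second probe from -1.36 to -1.19 and IKZF3 from -0.06 to -0.00357. IKZF3, not above background, read 0.26 with the processed signals, 0.0888 with those signals after loess and -0.11 with median centring; the cause was not tested. With an estimated correlation 0 lists passed and with fry 39, which tests another question. RPS20 read 0.63 when the filter on dim probes was lifted, because another, brighter probe then entered. Whether that probe had been left out as dim or for outlier flags was not examined. The other named genes kept their direction under each setting that gave a value, and 30 of 1725 such values missed the threshold, 14 of them without the array pairing and 10 against a fold of 1.5. For single lists 7 values missed and 11 newly passed the threshold (desmosome, p53 targets, CDK inhibitors, chromatin remodelling partners and housekeeping genes), and no list that passed changed direction. Signal over background limits the dim genes: the share of probes above it was lowest in replicate 2.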

Other observations

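The gene family tests were chosen only after the results were seen. Genes were grouped by symbol into 499 families of at least 5 measured members, and 3 passed camera. Pregnancy-specific glycoproteins (PSG), a cluster of placental immunoglobulin-type proteins on chromosome 19, had 7 of 7 measured members higher with Aiolos, with a median log2 ratio of 2.51 (limma camera adjusted p = 0.0184). That family had adjusted p = 0.995 with an estimated correlation. Its leader PSG8 was at 4.35 ± 0.30; these genes are close copies, and cross-hybridisation was not tested. Of the 7 members 6 were above background in the empty-vector channel on fewer than 3 arrays, PSG3 on none, and entered the test through the Aiolos channel, which favours a rise. The median stayed positive with median centring (2.55). Dual-specificity phosphatases (DUSP), several of which switch off MAP kinases, had 17 of 20 higher and 1, DUSP12 (-0.47), lower, with a median of 0.63, or 0.825 with median centring (adjusted p = 0.00602), and adjusted p = 0.995 with an estimated correlation. DUSP5 (2.71 ± 0.19), DUSP16 (2.38 ± 0.20) and DUSP1 (1.82 ± 0.06) led it, and DUSP1, DUSP4, DUSP5 and DUSP6 are also in the AP-1 and immediate early list. Cytochrome oxidase genes (COX) had 16 of 22 higher and none lower, with a median of 0.70, or 1.18 with median centring (adjusted p = 0.0313), and adjusted p = 0.995 with an estimated correlation; they overlap the respiratory chain list.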
